A study of Mus musculus with 9 samples.

How the data were processed

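Contacts of the mouse Dbp locus were measured by chromosome conformation capture-on-chip (4C) in embryonic fibroblasts synchronized with dexamethasone for 2 h. Per the labels' protocols, crosslinked chromatin was cut with HindIII and ligated. The product was cut with Csp6I, circularized and amplified by inverse PCR from Dbp. The 4C DNA was labelled with Cy5, and genomic DNA of the same cells, cut with both enzymes, was labelled with Cy3. Each of 9 samples was hybridized to 1 two-colour NimbleGen array. No dye swap or repeat array was used here.

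The 9 arrays formed 7 groups. Wild-type line 1 was harvested at circadian time (CT) 22, 26, 30, 34 and 46 h, the Bmal1-/- line at CT22 and CT34, and an independent wild-type line 2 at CT22 and CT34. Times follow the labels. In the file headers the names of the line 2 arrays carry 24 and 36, and which count was meant is not given in the sources used here. This bears on the pairing of the lines by time and on the rhythm fit. WT CT22 and WT CT34 thus had n = 2, with 1 array per line, and every other group had n = 1. Per the labels, line 1 and the Bmal1-/- line came from siblings of one mating scheme. Line 2 came from another cross. Genotype and the single Bmal1-/- line are therefore one factor. The lines were separate embryo cultures, so the spread between line 1 and line 2 includes culture and hybridization.

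The deposited values are log2 ratios of Cy5 over Cy3, 1 per probe, written by NimbleScan per the file headers. The authors' software shifted each array by its Tukey biweight mean, which the headers record. The log base is the convention of NimbleScan and is not written in the files. Every array held the same probes of 59 nt, 19355 on chromosome 7 and 365587 elsewhere, with a median of 5037 bp between the starts of neighbouring probes. The genome build, background correction and filters are not given in the sources used here. Coordinates are those of the files, 1-based, and chromosomes 20 and 21 keep the numbers of the files, which do not say which sex chromosome each is.

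Each array was centred on its median. Probes were averaged in non-overlapping windows of 100 kb with at least 5 probes, which gave 24953 windows with a median of 16 probes. A probe was called high when it exceeded the array's own 95th percentile, taken over probes off chromosome 7, the chromosome of the viewpoint. Contact windows were called by a one-sided binomial test of the number of high probes against the share of high probes off chromosome 7. Benjamini-Hochberg adjustment was applied per array, separately on chromosome 7 and elsewhere, at 0.05. Such a call describes 1 array and is no test between conditions. The viewpoint position was taken as the maximum of a running mean over 11 windows of the mean of 9 arrays.

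Window means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, adjusted p under 0.05). WT CT22 was compared with WT CT34 over 4 arrays. Bmal1-/- was compared with WT over 6 arrays with circadian time as a term. The genotype by time interaction used the same 6 arrays. A cosine and a sine term of 24 h were tested by an F test over 7 wild-type arrays with line as a term. The replicate number stands for the cell line, so it pairs samples across WT CT22 and WT CT34. The differences between the lines at CT22 and at CT34 correlated across windows (r = 0.748 over 24953 windows, and 0.536 over the 23644 off chromosome 7). The fit with line as a replicate block was an alternative.

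CT34 minus CT22 changes were correlated between the lines across windows off chromosome 7, with a null from 1000 circular shifts. Windows are not independent replicates. Array similarity, signal by distance and shares of high probes per chromosome are descriptions, and intervals of shares are exact Clopper-Pearson intervals at 95%, which cover counting error only. The number of arrays limits the precision of every comparison. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

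The analysis was tested on simulated data. With 200 windows changed among 24953, changes of 2 on the log2 scale were recovered in 83.3% for WT CT22 against CT34, in 97% for Bmal1-/- against WT and in 0% for the interaction. Changes of 1 were recovered in 8.96%, 61.2% and 0% in the same order. For the rhythm, a cosine term of 0.5 was recovered in 95.5%, and changes of the sine term were not simulated. In the data a window with a fitted amplitude of 0.96 had an adjusted p of 0.906 (limma). This recovery therefore does not show that rhythms of 0.5 were absent. Simulated noise was independent between arrays, so in fits without a term for line, differences between the lines were not simulated. Of all simulated calls, 11.0% were false for Bmal1-/- against WT (13 calls), 10.0% for the rhythm (22 calls) and 1.61% for WT CT22 against CT34 (1 call), where the threshold aims at 5%. In 1 Mb windows the false share was 8.06% for Bmal1-/- against WT over 6 arrays, and the fit of 7 arrays was not simulated. In permuted probes of the WT CT22 replicate 1 array, 0 of 23644 windows were called. Windows given 50% high probes were recovered in 86.5% and windows given 30% in 21.5%.

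The tests, window sizes, percentiles, scalings, leave-one-out fits, block fits and the rule for named regions were fixed before the data were examined. The regions named are the 10 on chromosome 7 over 1 Mb from the viewpoint and the 10 elsewhere, ranked by calls in wild-type arrays and then by share of high probes, and, where fewer than 5 windows passed a test, the 5 windows of smallest p. The choice of 1 Mb windows with line 1 alone followed a result of 0 windows for Bmal1-/- against WT in the fit fixed beforehand, and 26 fits of that comparison were made in all, besides those leaving out 1 array of the 7. Windows of 1 Mb with at least 50 probes, a fit of Bmal1-/- against the 5 line 1 arrays, a term for the style of the array name in the file headers, and the sharing of single probes between arrays were added after seeing the data. Those names came in 3 styles, carried by 4 line 1 arrays, by WT CT26 with both Bmal1-/- arrays, and by both line 2 arrays. Gene lists fixed beforehand were not run, because no annotation in the coordinates of the files was used here. Gene names come from a table of the GRCm38.p6 assembly, used for names and gene order only.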

Results

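The contacts of Dbp were profiled genome-wide in mouse embryonic fibroblasts, primary cells grown from embryos, at several circadian times after a dexamethasone pulse that synchronizes their clocks. Dbp encodes a transcription factor whose transcription follows the circadian clock, and Bmal1 encodes an activator of the core clock. In the GRCm38.p6 assembly Dbp lies on chromosome 7 between Car11 and Sphk2. The design asked how the contacts of this locus differ with circadian time and in cells without Bmal1. The 9 arrays comprised 5 of wild-type (WT) line 1, at circadian time (CT) 22, 26, 30, 34 and 46 h, 2 of a Bmal1-/- line and 2 of an independent WT line 2, the last 4 at CT22 and CT34. Times are those of the labels, and the array names of line 2 carry 24 and 36 in their place. Values are log2 ratios of 4C DNA over genomic DNA for 19355 probes on chromosome 7 and 365587 elsewhere per array. A single time point of a line is 1 array without replicate, so means and SDs over line 1 run over 5 circadian times.

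Line 2 had a narrower range of ratios than the other arrays. The SD over probes was 0.391 and 0.411 in line 2 at CT22 and CT34, against 0.825 to 0.929 in line 1 and 0.92 and 1.1 in Bmal1-/-. The 95th percentile off chromosome 7 lay at 0.51 and 0.52 in line 2, against 1.64 to 2.07 in line 1 and 2.16 and 2.73 in Bmal1-/-. Per the labels, line 2 was also grown with a different serum supplement.

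The strongest signal of every array lay on chromosome 7. The running mean peaked in the window from 45200001 to 45300000 or its neighbour from 45300001 to 45400000 in all 9 arrays, and this peak was taken as the viewpoint. Within 1 Mb of it the mean log2 ratio was 3.88 ± 0.17 (SD, n = 5 arrays) in line 1, 3.83 ± 0.20 (SD, n = 2) in Bmal1-/- and 1.67 ± 0.0055 (SD, n = 2) in line 2. In line 1 it was 2.85 ± 0.16 between 1 and 2 Mb, 1.27 ± 0.082 between 2 and 5 Mb and 0.88 ± 0.043 between 5 and 10 Mb. Farther away the signal did not keep falling: it was 1.41 ± 0.070 between 10 and 20 Mb and 1.34 ± 0.059 between 50 and 100 Mb. The same dip between 5 and 10 Mb was measured in Bmal1-/-, with 1.18 ± 0.21 there and 1.62 ± 0.17 between 10 and 20 Mb. In Bmal1-/- the signal between 50 and 100 Mb was 1.44 ± 0.24. Line 2 differed from this course: its signal was 0.33 ± 0.018 between 5 and 10 Mb and 0.41 ± 0.013 between 10 and 20 Mb, but 0.28 ± 0.050 between 20 and 50 Mb and 0.27 ± 0.057 between 50 and 100 Mb.

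**Figure D1:**
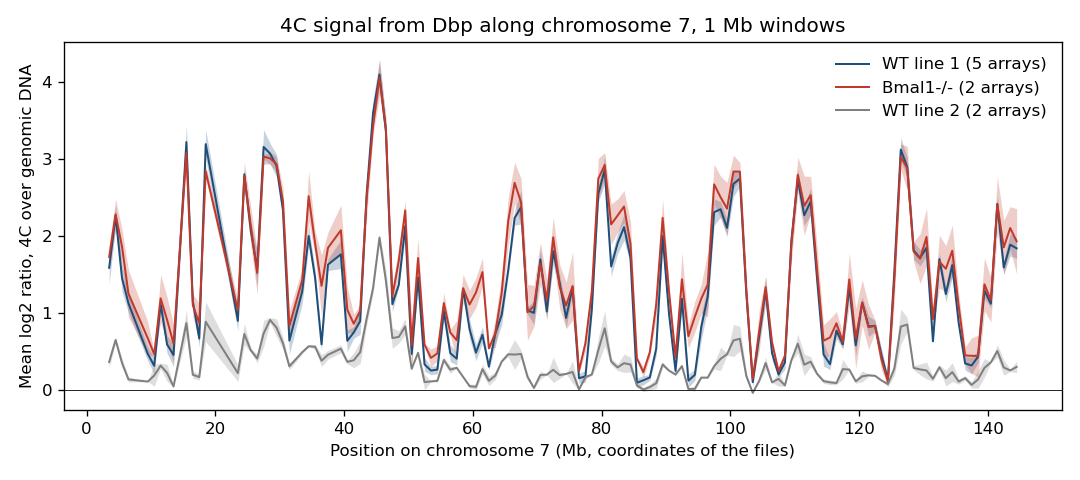
Mean log2 ratio of 4C over genomic DNA in 1 Mb windows (vertical axis) against position on chromosome 7 in Mb (horizontal axis), as lines for WT line 1 (5 arrays), Bmal1-/- (2 arrays) and WT line 2 (2 arrays), with bands of 1 SD over arrays. All lines peak near the viewpoint, and line 1 and Bmal1-/- return to high values in separate regions along the whole chromosome, while line 2 stays lower.

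Contacts on chromosome 7 formed separate regions that recurred at every time. Of 1309 windows of 100 kb, 257 were called in all 7 WT arrays, 21 of them within 1 Mb of the peak and 236 farther away, in 91 merged regions. In line 1 alone, 609 windows were called at all 5 times, and 579 of these were also called in both Bmal1-/- arrays. The region from 26900001 to 27100000, 18.1 Mb from the peak, had the highest share of high probes among the distant ones, with 87.0% ± 6.15 (SD, n = 5) in line 1 and means of 56.5% in line 2 and 73.9% in Bmal1-/-. The region from 126100001 to 126600000, 80.9 Mb away, had 80.8% ± 2.56 in line 1, 50.7% in line 2 and 72.6% in Bmal1-/-. The region from 140700001 to 140900000, 95.5 Mb away and near the distal end, had 78.4% ± 3.58 in line 1. On the centromere-proximal side, the regions from 3200001 to 3300000 and from 4200001 to 4700000 had 78.5% ± 6.44 and 79.7% ± 5.30. The remaining regions named by the same rule ran from 18100001 to 19000000, 24000001 to 24300000, 33800001 to 34100000, 37700001 to 38000000 and 46300001 to 47100000, with line 1 means from 79.2% to 86.3%. All 10 were called in all 9 arrays. They were chosen by calls and shares in WT arrays, which raises the WT shares in them, so lower shares in Bmal1-/- are no comparison of genotypes. The number of contact windows per array was 736 to 779 in line 1, 733 and 762 in Bmal1-/- and 383 and 476 in line 2. Tested against the share of high probes on chromosome 7 itself, a choice made after seeing the data, 34 windows remained in all 7 WT arrays.

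Off chromosome 7, the share of high probes was graded between chromosomes. Chromosome 7 held 36.1% ± 1.0 high probes in line 1 (SD, n = 5), 32.8% ± 0.98 in Bmal1-/- (n = 2) and 19.5% ± 1.8 in line 2 (n = 2). In line 1, chromosome 19 followed with 8.70% ± 0.51, then chromosome 11 with 8.04% ± 0.29, chromosome 15 with 6.97% ± 0.14, chromosome 17 with 6.63% ± 0.18 and chromosome 10 with 6.31% ± 0.12. The lowest shares among chromosomes with over 1000 probes were 2.64% ± 0.21 on chromosome 20 and 3.51% ± 0.21 on chromosome 3. In Bmal1-/-, chromosomes 19 and 11 had 8.10% ± 0.16 and 7.44% ± 0.34, and chromosome 20 had 3.29% ± 0.33. The order of 19 chromosomes correlated between line 1 and Bmal1-/- (Spearman's rho = 0.966, across chromosomes, which are not replicates) and between line 1 and line 2 (rho = 0.772). In line 2 the shares were flatter, with 5.76% ± 0.30 on chromosome 19 and 3.87% ± 0.045 on chromosome 20. For single arrays the exact interval for chromosome 7 was narrow, for example 35.4% to 36.8% at WT CT22 replicate 1.

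**Figure D2:**
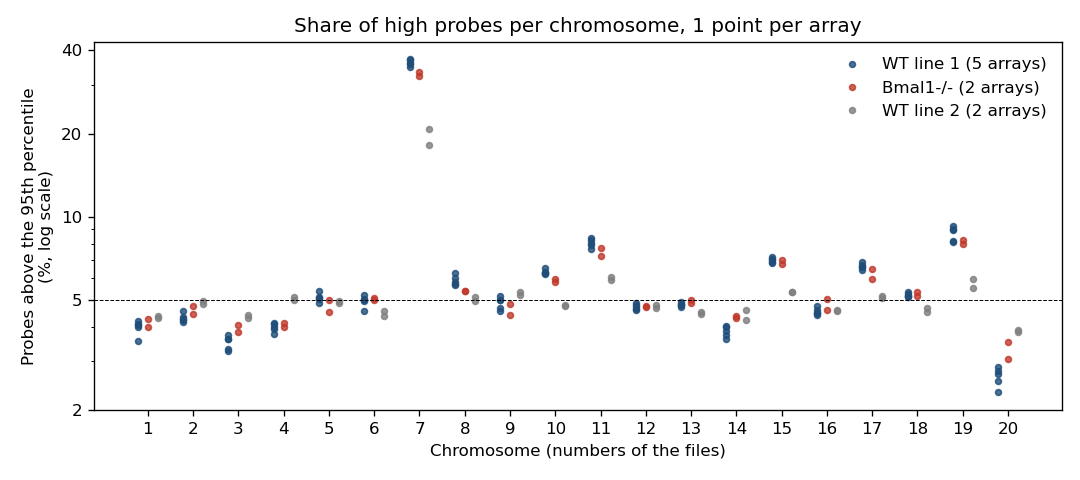
Share of probes above the array's own 95th percentile in percent (vertical axis, log scale) for each chromosome with over 1000 probes (horizontal axis, numbers of the files), 1 point per array, coloured by line. The dashed line marks 5%, chromosome 7 lies at 36.1% on average in line 1, and chromosomes 19 and 11 lead the others.

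Contact windows off chromosome 7 were few at 100 kb, where 21.5% of simulated windows with 30% high probes were recovered. The arrays of line 1 had 95, 142, 95, 40 and 58 of 23644 windows at CT22, 26, 30, 34 and 46, Bmal1-/- had 8 at CT22 and 43 at CT34, and line 2 had 0 at both times. In line 1, 79 windows were called in at least 2 arrays and 1 in all 5. WT CT22 and CT26 of line 1 shared 36 windows, against 0.571 expected if they were independent. Both arrays held the same probes, so this excess does not tell contacts from effects of the probes. Because line 2 had no calls, no region was called in every WT array, and the regions named are those called in most. Here adjacent windows called in at least 1 WT array were merged. An array counted as calling a region when it called any window of it, so arrays may have called different windows. Their choice rests on calls of line 1, which raises its shares in them relative to line 2 and Bmal1-/-. These shares are therefore no comparison of the lines. On chromosome 10, the region from 79900001 to 80200000 had 44.5% ± 4.47 high probes in line 1 (SD, n = 5), 21.2% in line 2 and 36.2% in Bmal1-/-. Chromosome 19 held the regions from 5000001 to 6400000, with 33.4% ± 5.15, from 4700001 to 4900000, with 32.4% ± 5.06, from 46300001 to 46700000, with 30.6% ± 6.03, and from 3900001 to 4400000, with 33.6% ± 7.44. On chromosome 17 the regions from 34400001 to 34800000 and from 35300001 to 35600000 had 32.8% ± 3.43 and 30.7% ± 7.05. The regions from 69500001 to 69700000 and from 5600001 to 5900000 on chromosome 11 had 35.6% ± 16.1 and 31.8% ± 8.65, and the region from 79400001 to 79600000 on chromosome 15 had 32.4% ± 6.72.

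In windows of 1 Mb, chosen after seeing the data, contact calls off chromosome 7 recurred between arrays. Of 2385 windows, 122 were called at all 5 times of line 1, against 0.0412 expected if the arrays were independent, and 84 of the 122 were also called in both Bmal1-/- arrays. All arrays held the same probes, so the excess over independence does not tell contacts from effects of the probes. Chromosome 11 held 25 of the 122 and chromosome 19 held 14. Line 2 had 13 calls at CT22 and 41 at CT34, and 7 windows were called in all 7 WT arrays. These 7 began at 5000001 on chromosome 19, 79000001 and 80000001 on chromosome 10, 76000001 and 97000001 on chromosome 15, 34000001 on chromosome 17 and 102000001 on chromosome 11. The window on chromosome 19 had 32.3% ± 4.12 high probes in line 1 and means of 21.1% in line 2 and 26.3% in Bmal1-/-. It was picked for its WT calls, so these shares are no comparison of genotypes.

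Arrays of line 1 and of Bmal1-/- resembled each other more than either resembled line 2. Over windows off chromosome 7, the median r across windows was 0.639 for the 10 pairs of line 1 arrays (0.599 to 0.67), 0.651 for the 10 pairs of line 1 with Bmal1-/- (0.543 to 0.712) and 0.299 for the 10 pairs of line 1 with line 2. Bmal1-/- CT22 had r of 0.543 to 0.562 with the line 1 arrays other than WT CT34, below every line 1 pair, and the value with WT CT34 was 0.664. On chromosome 7 the medians were 0.938, 0.918 and 0.693. These are correlations across windows, which are not independent replicates. At single probes off chromosome 7, a measure added after seeing the data, WT CT34 of line 1 stood apart in its sharing with the Bmal1-/- arrays. It shared 8.72 times as many high probes with Bmal1-/- CT22 as independence would give and 8.47 times as many with Bmal1-/- CT34, and the Bmal1-/- arrays shared 6.59 times as many with each other. The other 18 pairs of these 7 arrays lay between 3.65 and 5.46. The pair of line 2 arrays shared 9.75 times as many, with a ratio of 1.14 at the next probe. At the next probe along the chromosome, the WT CT34 pairs with Bmal1-/- had ratios of 1.47 and 1.60, and the other 18 pairs had 1.48 to 1.91. At the same probe, once probes high on WT CT34 were left out, the 2 Bmal1-/- arrays shared 4.11 times as many as independence would give. The 14 other pairs then lay between 2.97 and 5.6.

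**Figure D3:**
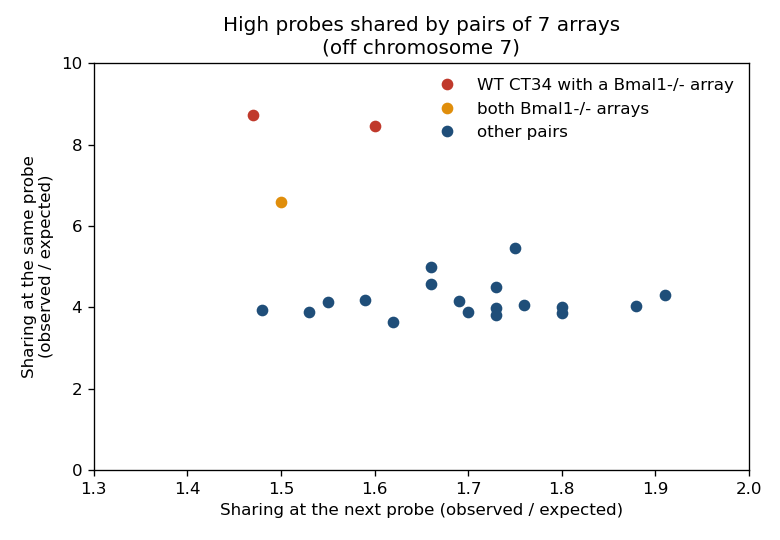
Observed over expected sharing of high probes at the same probe (vertical axis) against sharing at the next probe along the chromosome (horizontal axis) for all pairs of the 5 line 1 and 2 Bmal1-/- arrays, off chromosome 7. The points of WT CT34 with a Bmal1-/- array lie at 8.72 and 8.47 on the vertical axis, above the 3.65 to 5.46 of the 18 other pairs, and not apart on the horizontal axis.

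No window passed the test of CT22 against CT34 in WT cells, the 5 windows of smallest p included. On chromosome 7, the window from 60000001 to 60100000 had mean log2 ratios of 0.55 at CT22 and -0.09 at CT34, a difference of -0.64 with SE 0.12, and the window from 90400001 to 90500000 had 0.50 and -0.0045. On chromosome 16, the window from 86800001 to 86900000 had 0.44 at CT22 and 0.02 at CT34, and that from 93300001 to 93400000 had 0.03 and 0.46. The window from 23300001 to 23400000 on chromosome 7 had -0.09 and 0.38. The adjusted p was 1 for each (limma, n = 2 per time). Line 1 at CT46, which shares the phase of CT22, was not in this test. It had 0.69, 0.6, 0.15 and 0.11 in the windows starting at 60000001, 90400001, 86800001 and 23300001. In that starting at 93300001 it had 0.56, near the 0.52 of line 1 at CT34. Over 24953 windows, 0 passed and 73 had an unadjusted p under 0.05, where 1248 would be expected by chance. That number was 24 and 29 without the line 1 array at CT22 or CT34, and 666 and 886 without that of line 2. With the line as a replicate block, 0 passed and 584 had an unadjusted p under 0.05. The test recovered 8.96% of simulated changes of 1 on the log2 scale, so most such differences at single windows were not detectable. In 1 Mb windows, added after seeing the data, 0 windows passed and 0 had an unadjusted p under 0.05 (limma), where 125.9 would be expected by chance. There 65.7% of simulated changes of 0.5 were recovered, but the simulation held no differences between the lines. No 1 Mb fit of this comparison with line as a term was made, so the count of 0 does not show that contacts were unchanged.

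The time course asked whether contacts follow a 24 h cycle. No 24 h rhythm passed the test over the 7 WT arrays. Of the 5 windows of smallest p, which did not pass, 4 were on chromosome 7. The window from 19000001 to 19100000 had an amplitude of 0.96 with a fitted peak at 4.55 h of the 24 h cycle, and line 1 values of 1.85, 2.83, 2.96, 2.24 and 2.00 at CT22, 26, 30, 34 and 46. The windows from 72400001 to 72500000, 18400001 to 18500000 and 85300001 to 85400000 had amplitudes of 1.04, 0.74 and 0.84 with peaks at 14.5, 14.6 and 14.9 h. These 3 peaks fall in the 12 h from 10 to 22 h of the cycle in which no WT array was taken, so they are extrapolated. On chromosome 19, the window from 38000001 to 38100000 had an amplitude of 0.97 with a peak at 4.22 h. The adjusted p was 0.906 for each (limma), 0 windows passed, and 1211 had an unadjusted p under 0.05, or 782 without WT CT34 of line 1. With line 2 at the times its array names carry, added after seeing the data, 0 passed and 901 had an unadjusted p under 0.05. In line 1 alone, 0 passed and 1476 had an unadjusted p under 0.05. CT22 and CT46, which share a phase, had r = 0.658 across windows off chromosome 7, the third highest of the 10 line 1 pairs, after CT30 with CT46 (0.67) and CT22 with CT30 (0.665).

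In the comparison fixed beforehand, no region differed between Bmal1-/- and WT cells past the threshold. In windows of 100 kb over 6 arrays, 0 passed (limma), and the 5 of smallest p, each with an adjusted p of 0.281, were all higher in Bmal1-/-. On chromosome 7, the window from 94800001 to 94900000 had a mean of 1.37 in Bmal1-/- (n = 2) and 0.06 in WT (n = 4), a difference of 1.31 with SE 0.13. The windows from 93700001 to 93800000, 36900001 to 37000000 and 62100001 to 62200000 differed by 0.90, 1.33 and 0.79. On chromosome 12 the window from 88400001 to 88500000, with 5 probes, differed by 1.13. The line 1 arrays at CT26, CT30 and CT46 were not in this fit. At CT30 line 1 had 1.2, 0.63 and 0.67 in the windows starting at 36900001, 62100001 and 88400001. It had 0.13 and 0.04 in those starting at 93700001 and 94800001. At CT26, on the array that shares its name style with both Bmal1-/- arrays, line 1 had 0.415 at 93700001. The mean there was 0.77 in Bmal1-/- and -0.13 in the WT arrays of the fit. At 94800001, 36900001, 62100001 and 88400001 line 1 had 0.164, 0.895, 0.588 and 0.362 at CT26. At CT46 it had 0.00714 at 93700001 and, in the same order, 0.258, 0.205, 0.494 and 0.406 at the others. An unadjusted p under 0.05 was reached by 3606 windows, where chance gives 1248, and 3576 of them were higher in Bmal1-/- and 30 lower. With quantile normalization it was reached by 1182, of which 779 were higher and 403 lower. Without Bmal1-/- CT34 the number was 1457, and without line 2 at CT22 it was 1917. With line 1 as the only WT line, the fit that serves as replicate block, it was 1631, of which 1540 were higher and 91 lower, and with a term for line 2, added after seeing the data, it was 2825, of which 2610 were higher and 215 lower. Both gave 0 windows past the threshold.

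Larger windows and line 1 alone were then tried, after the comparison above had given 0. Bmal1-/- was set against WT in 26 fits in all, 17 fixed beforehand and 9 added. Of these, 20 gave 0 windows, among them 6 of the 9 added. Of the 17 fixed beforehand, 3 gave windows: 16 with the window median, 379 with the trend and robust options of limma, and 288 with the share of high probes, where 277 had a residual variance of 0. The 3 added fits that gave windows are those of 1 Mb windows with 5 line 1 and 2 Bmal1-/- arrays, without a term for time, and they differ only in scaling. With circadian time matched, no 1 Mb window passed: line 1 and Bmal1-/- at CT22 and CT34 alone (4 arrays) gave 0 windows, 321 with an unadjusted p under 0.05 and a smallest adjusted p of 0.388, and the 6 arrays of the comparison fixed beforehand gave 0, 629 and 0.19 (limma). The fit of WT CT26 against both Bmal1-/- arrays is counted among the 20, but it rests on 1 WT array and 1 residual degree of freedom. Its lack of calls therefore says little about the genotypes. The fit of 4 arrays also had 1 residual degree of freedom. Adjusted p values below cover the windows of 1 fit and not this search. In these fits 33 of 2518 windows were higher in Bmal1-/- under median centring, scaling by the median absolute deviation and quantile normalization alike (limma, adjusted p under 0.05).

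Of the 33 windows, 10 lay on chromosome 7, and those named here were chosen after their values were seen. The window starting at 94000001 had log2 ratios of 0.81 and 1.09 in Bmal1-/- at CT22 and CT34, against 0.20 ± 0.072 in line 1 (SD, n = 5), with an adjusted p of 0.0045 (limma). The windows starting at 60000001 and 61000001 differed by 0.78 and 0.81, with an adjusted p of 0.0045 for both (limma). Those starting at 35000001, 36000001, 65000001, 77000001, 81000001, 88000001 and 93000001 differed by 0.43 to 0.76. With quantile normalization the differences of the 10 windows were smaller, at 0.18 to 0.51. The 23 others lay off chromosome 7, among them 5 on chromosome 15, and differed by 0.27 to 0.43 with median centring and by 0.15 to 0.22 with quantile normalization. These differences include a shift of 0.10 in the median of all windows with median centring, which was 0.003 with quantile normalization. Median centring called 254 windows higher and 0 lower, scaling by the median absolute deviation 387 and 0, and quantile normalization 33 and 23. These numbers depended on single arrays. The 254 became 15 without Bmal1-/- CT34 and 923 without Bmal1-/- CT22, and 27 to 142 without a line 1 array. The 387 became 37 and 186 without these Bmal1-/- arrays and 88 to 496 without a line 1 array. With quantile normalization 22 higher and 20 lower were called without Bmal1-/- CT34, 6 and 3 without Bmal1-/- CT22, and 37 and 34 without WT CT34. Of the 23 lower ones, 10 were on chromosome 7 and 7 on chromosome 4, and none passed with median centring. Of the 33 windows, 14 were called again under all 3 scalings without WT CT22, 12 without WT CT26, 12 without WT CT30, 30 without WT CT34, 16 without WT CT46, 6 without Bmal1-/- CT22 and 11 without Bmal1-/- CT34. Of the 10 on chromosome 7, 7 to 10 were called again without a line 1 array. Leaving out a Bmal1-/- array leaves 1 array in that group, and the spread then comes from line 1 alone. The counts without a Bmal1-/- array are therefore no measure of how the Bmal1-/- arrays vary. With a term for the style of the array name, which WT CT26 shared with both Bmal1-/- arrays, 0 windows passed and 686 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0659 (limma). In that fit the differences of the 10 windows on chromosome 7, which then rest on WT CT26 alone, were 0.41 to 0.94 with SE 0.098 to 0.19, against SE 0.063 to 0.12 without the term.

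**Figure D4:**
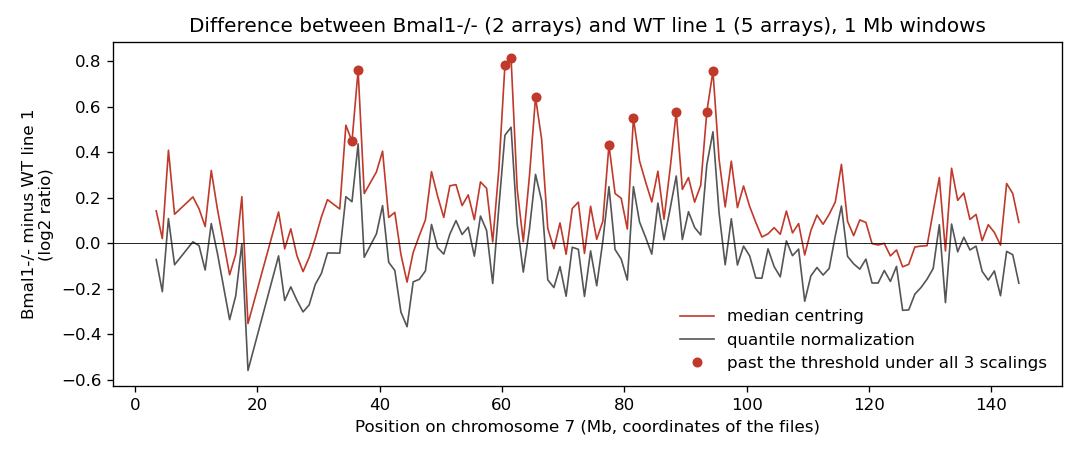
Difference in log2 ratio between Bmal1-/- (2 arrays) and WT line 1 (5 arrays) in 1 Mb windows (vertical axis) along chromosome 7 in Mb (horizontal axis), with median centring and with quantile normalization. Points mark the 10 windows past the threshold under all 3 scalings in a fit added after seeing the data, with differences of 0.43 to 0.81 with median centring.

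In the main fit no window passed the test of whether the change from CT22 to CT34 differed between genotypes. At 100 kb this fit could not be expected to find one. On simulated data it recovered 0% of changes of 2 on the log2 scale, so the count of 0 does not show that the genotypes changed alike. Of the other settings fixed beforehand, the trend and robust options of limma called 101 windows, 64 with a positive and 37 with a negative interaction. The share of high probes called 2181, all with a residual variance of 0. In 1 Mb windows, added after seeing the data, where 67.2% of simulated changes of 1 were recovered, 0 windows passed (limma). There 11 had an unadjusted p under 0.05, where 125.9 would be expected by chance, and the simulation held no differences between the lines. The 5 windows of smallest p had an adjusted p of 0.93 each (limma, 6 arrays). On chromosome 16, the window from 16000001 to 16100000 had log2 ratios of 2.03 at CT22 and 0.60 at CT34 in Bmal1-/-, against means of 0.07 and 0.20 in WT. On chromosome 7, the window from 60000001 to 60100000 had -0.04 and 0.82 in Bmal1-/- against 0.55 and -0.09 in WT. The windows starting at 12800001 on chromosome 8, 145100001 on chromosome 6 and 184300001 on chromosome 1 had interaction values of 1.16, 1.41 and 1.45. Over 24953 windows, 0 passed and 1110 had an unadjusted p under 0.05, with 345 to 1198 when 1 WT array was left out. With the line as a replicate block, on 1 residual degree of freedom, 0 passed and 3689 had an unadjusted p under 0.05. Of these, 3005 had a positive and 684 a negative interaction, and chance would give 1248 in all.

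The CT34 minus CT22 changes of the 2 WT lines showed no correlation past the threshold across 23644 windows off chromosome 7, and windows are not independent replicates. Pearson's r was -0.000557 and Spearman's rho -0.00243 (circular-shift permutation p = 0.93, adjusted over 3 pairs 0.93). Line 1 and Bmal1-/- had r = 0.0126 and rho = 0.0276 (permutation p = 0.061, adjusted 0.091). Line 2 and Bmal1-/- had r = 0.0366 and rho = 0.0266 (permutation p = 0.001, adjusted 0.003), the smallest p that 1000 shifts can give. The correlation of line 1 with Bmal1-/- turned to -0.0295 with quantile normalization (permutation p = 0.001, adjusted 0.003, where adjusted values over the other settings ran from 0.003 to 0.83), and that of line 2 with Bmal1-/- was 0.0151 (adjusted 0.037).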

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

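The comparison of directions by chromosome was made after the shares were known. The difference between genotypes was not tested for these shares. The share of high probes changed from CT22 to CT34 in one direction in both WT lines and in the other direction in Bmal1-/- for 9 of 20 chromosomes, where chance alone would give about 5, and shares of different chromosomes are not independent. In Bmal1-/- the share was lower at CT34 on chromosomes 1 (-0.262 percentage points), 2 (-0.309), 3 (-0.22), 14 (-0.0451) and 16 (-0.462), and it was higher in both WT lines. In Bmal1-/- the share was higher at CT34 on chromosomes 5 (0.463), 11 (0.485), 15 (0.198) and 17 (0.509), and it was lower in both WT lines. On chromosome 11 the WT changes were -0.622 in line 1 and -0.147 in line 2. On chromosome 17 they were -0.302 and -0.103. Some WT changes were close to none, with -0.0447 and -0.0384 on chromosome 15 and 0.0134 in line 2 on chromosome 16. Each change is 1 array minus 1 array. In Bmal1-/- the exact intervals at CT22 and CT34 overlapped on all 9 chromosomes, for example 6.83% to 7.58% and 7.3% to 8.08% on chromosome 11. The directions therefore do not show a reversal in Bmal1-/-.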

How the results depend on the processing

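Windows of 1 Mb, the null from chromosome 7 itself and the fits of 7 arrays were added after seeing the data, and the cause of a change was not tested unless given. The array number, 1 per line and time, and the narrow range of line 2 limit every comparison. Contact windows on chromosome 7 had a median of 747 per array. The median was 1158 with 50 kb, 354 with 250 kb and 115 with 1 Mb windows, which change the number of windows, and 177 against the share of chromosome 7 itself. Off chromosome 7 the median of 43 became 120 with the 90th percentile, 4 with the 98th, 17 with the percentile over all probes, 7 with 50 kb, 169 with 250 kb, 16 at an adjusted p of 0.01, 238 with 1 Mb and 381 for the window mean against random draws. The 257 windows of chromosome 7 called in all WT arrays became 164 at an adjusted p of 0.01, 95 with 1 Mb, 34 against the share of chromosome 7 itself, 425 with random draws and 463 when neighbouring windows counted as shared. The 79 windows off chromosome 7 called in at least 2 line 1 arrays became, for the 90th percentile, 98th percentile, all probes, 50 kb, 250 kb, adjusted p of 0.01, 1 Mb, random draws and neighbouring windows, 217, 4, 17, 10, 309, 18, 320, 399 and 153.

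The count of 0 for WT CT22 against CT34 became 993 with the share of high probes as window value, that for Bmal1-/- against WT 288, that for the interaction 2181 and that for the rhythm 278. In these, 993, 277, 2181 and 272 calls were windows with a residual variance of 0, where arrays hold equal shares, so these calls come from how the value is built, and the cause of the remaining ones was not tested. For Bmal1-/- against WT, the window median gave 16 and eBayes with trend and robust 379, and the latter gave 101 for the interaction. Of 26 fits of Bmal1-/- against WT, 20 gave 0. In 1 Mb windows over 7 arrays Bmal1-/- against WT gave 254 with median centring, 387 with scaling by the median absolute deviation and 56 with quantile normalization. Leaving out 1 array turned the 254 higher windows to 15 to 923 and the 387 to 37 to 496. Leaving out each array in turn gave 0 in each of the 4 tests on 100 kb windows. In 1 Mb windows over 7 arrays, 33 were higher in Bmal1-/- under all 3 scalings, and fits that left out 1 array gave 6 to 36 such windows, of which 6 to 30 were among the 33. For the interaction, leaving out a Bmal1-/- array allows no fit, and line 1 with Bmal1-/- alone leaves no residual degrees of freedom. The replicate block (line as a term) gave 0 for WT CT22 against CT34 and for the interaction, line 1 alone as replicate block gave 0 for Bmal1-/- against WT, and without the replicate block the rhythm count was 0. Among named windows, 1 Mb windows turned the WT difference at 90400001 on chromosome 7 to 0.0406 and the interaction at 16000001 on chromosome 16 to 0.00677, and the share of high probes gave 0 for the difference at 88400001 on chromosome 12.

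The correlation of changes between line 1 and Bmal1-/- was -0.0295 with quantile normalization, -0.0262 with the share of high probes and 0.0509 with 1 Mb windows. That between line 2 and Bmal1-/- was 0.0209 in contact windows only and 0.119 with 1 Mb windows. The median r of line 1 pairs, of line 1 with Bmal1-/- and of line 1 with line 2 was 0.453, 0.455 and 0.156 with the share of high probes, 0.517, 0.535 and 0.2 with 50 kb, 0.79, 0.77 and 0.457 with 250 kb, 0.294, 0.305 and 0.0603 at single probes and 0.919, 0.881 and 0.702 with 1 Mb windows. As a share of high probes, the fall from under 1 Mb to 50 Mb and more was 55.7 percentage points in line 1, 62.9 in line 2 and 54.4 in Bmal1-/-. High probes on chromosome 7 in line 1 were 46.3% with the 90th and 23.4% with the 98th percentile, with a mean log2 ratio of 1.36. On chromosome 19 they were 15.4% and 3.51%, with a mean of 0.254. Gene lists with windows of 50 and 200 kb were not run.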

Other observations

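All tests in this part were chosen after the results were seen. The 10 windows of chromosome 7 higher in Bmal1-/- spanned low and intermediate signal in line 1. The windows starting at 93000001, 94000001 and 77000001 had line 1 means of 0.12, 0.20 and 0.18, against 0.70, 0.95 and 0.61 in Bmal1-/-. Those starting at 35000001, 65000001 and 81000001 had 1.46, 1.55 and 1.60 in line 1, against 1.90, 2.19 and 2.15 in Bmal1-/-. In the window starting at 18000001, with 3.19 in line 1, Bmal1-/- had 2.84. Line 2 had 0.0124 and 0.0137 in the windows starting at 93000001 and 94000001.

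The higher windows in Bmal1-/- were found in a fit kept after a search, so chance was not excluded: the 20 other choices of 2 of the 7 arrays gave at most 9 higher windows with median centring, for WT CT46 with Bmal1-/- CT34, and 0 with quantile normalization, but the fit had been kept for its calls with the real choice. A wider spread of ratios over whole Bmal1-/- arrays is argued against as the whole cause. With one distribution for all arrays, 10 of 22 windows on chromosome 7 and 23 of 232 elsewhere were still higher. It may account for the rest, as the differences of the 10 were 0.43 to 0.81 before and 0.18 to 0.51 after. A spread that differs with signal on chromosome 7 is not excluded, because quantile normalization matches whole arrays. With it, 10 other windows of chromosome 7 were lower in Bmal1-/-. Their line 1 means were 1.15 to 3.19, against 0.12 to 1.60 in the 10 higher ones. An effect of the array-name style cannot be told apart from the genotype, because a single WT array shared that style. In 8 windows of chromosome 7 chosen without WT CT26, this array covered a median of -0.012 of the way from the other 4 line 1 arrays to Bmal1-/-. The SE of 0.047 runs over these windows of 1 array, which are not replicates of the style. With the style as a term 0 windows passed, on 4 residual degrees of freedom in place of 5. For the 10 windows the SE was 0.098 to 0.19 in place of 0.063 to 0.12, while their differences were 0.41 to 0.94. Why the other windows no longer passed was not tested. Other differences of the single Bmal1-/- line, and a haplotype of chromosome 7, where Bmal1 lies as Dbp does, were not tested, so the pattern stays a hypothesis.

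The single high probes that WT CT34 of line 1 shared with the Bmal1-/- arrays were weighed too. Similar contact regions cannot be told apart from a technical origin: the mean at the next probe was 1.54, within the 1.48 to 1.91 of the other pairs, but the line 2 arrays, of one cell line, shared 9.75 at single probes and 1.14 at the next. A contact set of the Bmal1-/- cells and transfer of 4C DNA between samples were not tested.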
